A study of Mus musculus with 14 samples.

How the data were processed

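Single-cell 3' RNA sequencing was done on a 10x Genomics Chromium instrument in 14 libraries of C57BL/6 mouse cells, with 2 libraries in each of 7 groups. The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and cell barcode, with no normalisation, for the barcodes the authors called as cells. The labels name the genome build mm10. Per the file headers, replicate 1 of every motor neuron group carries the software version 3.1.0 and a gene table of 28001 entries, whereas replicate 2 of every motor neuron group was made with Cell Ranger 4.0.0 and a table of 28002 entries. The replicate number of these 8 libraries therefore coincides with the software. Matrigel replicate 1 was made with Cell Ranger 5.0.1 (28002 entries) and Matrigel replicate 2 with Cell Ranger 6.0.1 (32285 entries). Cell Ranger 6.0.1 also made the induced cardiomyocyte libraries, with 28002 entries in replicate 1 and 32285 in replicate 2. For standard endoderm progenitor replicate 1 the labels name Cell Ranger with a doubtful version, and for replicate 2 the aligner and its version are not given in the sources used here. Genes were matched by Ensembl identifier, which left 28001 identifiers shared by the motor neuron libraries, 27040 by the endoderm progenitor libraries and 27040 by the cardiomyocyte libraries. Coordinates are those of GENCODE vM21 on GRCm38 (mm10), in which 14783 of 14827 tested motor neuron genes and 14102 of 14108 tested endoderm progenitor genes were found by identifier.

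Cells were kept with 1000 or more UMIs, 500 or more genes and a mitochondrial share of UMIs of 20% or less. Doublets were searched per library with scrublet at an expected rate of 0.06. It marked fewer than 0.5% of the cells of every library, so the search did not work and doublets remain in the data. Counts were then summed over the kept cells of each library. The unit of replication was the library. Differential expression was tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood fit with robust dispersion, TMM normalisation, filterByExpr) on a model with 1 mean per group, and p-values were adjusted over all tested genes by the Benjamini-Hochberg method at 0.05. In the motor neuron libraries the contrasts were retinoic acid, smoothened agonist, their interaction and the single effects, and in the endoderm progenitor libraries Matrigel against standard culture. Fold changes are given on the log2 scale with an approximate standard error (SE). This SE is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. Levels are given as CPM (UMIs of a gene scaled to a common library total) with the SD between libraries. Where every library of a group had 0 UMIs, a fold is a lower bound against a floor of 3 counts over the group. Where a group had 1 to 3 UMIs, the ratio of counts is given with its exact 95% interval. Intervals and floors cover counting error only.

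Before the data were examined, 40 gene lists, the contrasts, the tests, the cell filter, the alternatives and the rule for naming genes were fixed. Lists with 5 or more tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over lists, and again with the correlation estimated from the data. The rule named, per contrast, up to 10 genes in each direction with the largest fold change among those that passed, with a mean of at least 10 CPM on the higher side and separated libraries. It left out predicted, mitochondrial and ribosomal protein genes, added up to 4 members per list with the smallest p-values, and added a fixed set of markers. Genes named outside this rule are identified where they appear.

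Cells were clustered per system with scanpy 1.11.5 (10000 counts per cell, log transform, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.8, seed 0), without integration of libraries. Patterning and motor neuron lists were left out of the variable genes of the motor neuron system. A cluster took the name of a marker list whose members had a mean log2 ratio of 0.5 or more over the other cells (pseudocount 5 CPM), with at least 3 markers in at least 10% of its cells, and a median of 2000 or more UMIs. After the clusters had been seen, naming was restricted to the lists that apply to each system, and cardiomyocyte cluster 9, led by the atrial list, was counted with the cardiomyocyte-like cells. Shares of cells with a UMI of a gene were measured after each cell had been thinned to 2000 UMIs, with cells below that depth left out. Shares were compared with two-sided exact permutation tests over 70 arrangements of 4 against 4 libraries, whose smallest p is 0.0286, and adjusted over the 84 measures tested per factor. Of the genes measured as shares, Slc18a3, Lhx2, Otx2 and Ttr were chosen after the data had been seen.

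The alternatives tried were DESeq2 size factors, the DESeq2 1.42.0 test, no low-count filter, the replicate number as a block, a minimum absolute log2 fold change of 1, library sums thinned to the smallest, all deposited barcodes, a stricter cell filter (2000 UMIs and 10% mitochondrial), marked doublets left out, Leiden resolution 0.4, thinning to 1000 UMIs, and each library left out in turn. The fit was tested on simulated data. In simulations at the size of the retinoic acid contrast it recovered 83.3% of genes changed 4-fold and 25.4% of those changed 2-fold without calling an unchanged gene. With the replicate block it recovered 100% of both while calling 20 unchanged genes. These simulated counts held a replicate shift of the form that the block fits, which favours the block by construction. In the real motor neuron libraries the replicate differences correlated between groups at a Pearson r of 0.623 to 0.695. At the size of the Matrigel contrast the fit recovered 31.3% of genes changed 4-fold, 95.5% at 16-fold and 100% at 64-fold, with 19 unchanged genes called. The folds of the Matrigel simulation were raised after smaller ones gave no recovery. The single-cell steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and leidenalg 0.10.2.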

Results

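Messenger RNA was counted in single cells from 3 mouse systems of directed cell fate. Motor neurons were programmed from embryonic stem cells with transcription factors (TF) in 4 groups: TF alone, TF with retinoic acid (TF+RA), TF with smoothened agonist (TF+SAG), and TF with both (TF+RA+SAG). Retinoic acid is a vitamin A derivative that gives neural cells a caudal position, and smoothened agonist activates the Hedgehog pathway, which gives them a ventral position. Induced endoderm progenitors, converted from embryonic fibroblasts and expanded in culture, were sampled in standard culture and in a Matrigel sandwich, in which cells lie between layers of a basement membrane extract. Induced cardiomyocytes were sampled at day 14, with no group to compare them with. Each of the 7 groups had 2 libraries. The labels do not say whether replicates are separate cultures, so p-values measure the spread between these samples, which may be technical. After the cell filter, motor neuron libraries held 1222 to 16750 cells and 19157047 to 69622103 UMIs. TF+RA replicate 1 differed from the rest in depth, with a median of 1375 UMIs per cell against 7000 to 14165.5 in the other 7 motor neuron libraries. Endoderm progenitor libraries held 2034 and 7765 cells in standard culture (10685012 and 77056669 UMIs) and 8194 and 5719 cells in Matrigel (111634044 and 45562291 UMIs). The cardiomyocyte libraries held 1412 cells with 8654550 UMIs and 4350 cells with 48010385 UMIs. Whether counting used the strand of a read is not given in the sources used here. Counts of Hoxb5, Hoxb6 and their antisense transcript Hoxb5os, of Gli1 and Arhgap9, and of Rarb and Top2b are therefore uncertain where these genes overlap, as are those of Chat and Slc18a3, which overlap on 1 strand.

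The retinoic acid contrast asks how RA changes programmed motor neurons, averaged over cultures with and without SAG (4 libraries on each side). RA raised all tested Hox genes of paralogue groups 1 to 5 and lowered some genes of the fore- and midbrain. Hoxb4 and Hoxc4, which set position in the hindbrain and cervical spinal cord, rose from less than 1 CPM to more than 200 CPM. Chat, which encodes the enzyme that makes acetylcholine, and Slit2, a secreted axon guidance cue, also rose. Otx2 and Six3, transcription factors of the fore- and midbrain, and Cartpt, a neuropeptide precursor, fell, as did Pou5f1, a transcription factor of pluripotent cells.

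Of 14827 tested genes, 1843 passed at an adjusted p of 0.05 (edgeR quasi-likelihood, Benjamini-Hochberg), 943 higher and 900 lower with RA. With the replicate number as a block the count was 5868 (3125 higher, 2743 lower). It fell to 1228 without TF replicate 1, to 1136 without TF+RA+SAG replicate 1 and to 1175 without TF+RA+SAG replicate 2. All 20 genes with the largest changes passed in every such omission. Hoxb4 (ENSMUSG00000038692, chromosome 11, 96318267 to 96321638, plus strand) was at 288 ± 33.6 CPM (SD, n = 4) with RA and 0.312 ± 0.183 CPM (n = 4) without, a log2 fold change of 10.04 ± 0.26 (SE) with an edgeR adjusted p of 7.0e-06. Hoxc4 (ENSMUSG00000075394, chromosome 15, 103018934 to 103036852, plus strand) rose by 9.46 ± 0.24 to 216 ± 38.4 CPM. Hoxb5 (ENSMUSG00000038700, chromosome 11, 96303336 to 96306121, plus strand) rose by 12.81 ± 0.35 to 655 ± 144 CPM, and Hoxb8 by 13.57 ± 0.60 to 198 ± 65.8 CPM. Hoxb6 (ENSMUSG00000000690, chromosome 11, 96292476 to 96301569, plus strand) had 73288 UMIs with RA and 3 without, a ratio of 14755 (95% interval 5049 to 71550). Hoxb3 had 3 UMIs without RA, with a ratio of 2832 (969 to 13732). Hoxd4 was at 43.5 ± 16.02 CPM with RA and had no UMI without, which makes it at least 1568-fold higher, and Hoxb5os was at least 3017-fold higher. Cyp26b1, which degrades retinoic acid (ENSMUSG00000063415, chromosome 6, 84571414 to 84593908, minus strand), rose by 11.01 ± 0.48 from 0.122 to 259 ± 118 CPM.

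Rarb, a retinoic acid receptor (ENSMUSG00000017491, chromosome 14, 16430839 to 16819156, minus strand), rose from 4.56 ± 1.15 to 92.1 ± 3.88 CPM (log2 fold change 4.33 ± 0.22, edgeR adjusted p 7.7e-05). Dhrs3, which reduces retinaldehyde, rose by 4.27 ± 0.21. Meis1, a cofactor of Hox proteins, rose by 2.81 ± 0.16 from 33.9 to 238 ± 33.6 CPM, and Cyp26a1 by 2.82 ± 0.52 to 106 ± 66.8 CPM. Chat (ENSMUSG00000021919, chromosome 14, 32408203 to 32465989, minus strand) rose from 0.667 ± 0.226 to 51.5 ± 20.05 CPM (6.26 ± 0.32, adjusted p 7.7e-05). Slit2 (ENSMUSG00000031558, chromosome 5, 47983138 to 48307733, plus strand) rose from 63.0 ± 13.1 to 1426 ± 58.2 CPM (4.50 ± 0.22). Prph, a neurofilament protein, rose by 3.15 ± 0.24 and Mecom, a transcription factor of motor column identity, by 4.74 ± 0.31. Several core motor neuron regulators did not pass. The programming factors are not named here, so whether counts of these regulators include introduced copies cannot be told. Mnx1 was at 63.3 ± 23.5 CPM with RA and 26.0 ± 7.99 without (1.28 ± 0.33, adjusted p 0.0502), and at an adjusted p of 1.4e-07 with the replicate block. Isl1 had a log2 fold change of 0.35 (adjusted p 0.194; 0.0041 with the block), Lhx3 of 0.47 and Neurog2 of -0.20 (0.585; 0.0379 with the block). Tubb3, a tubulin of all neurons, was at 679.5 ± 255 CPM with RA and 600.4 ± 142 CPM without.

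Among the genes that fell, Otx2 (ENSMUSG00000021848, chromosome 14, 48657677 to 48673819, minus strand) was at 0.235 ± 0.275 CPM with RA and 36.2 ± 11.5 without, a log2 fold change of -7.44 ± 0.65. Six3 (ENSMUSG00000038805, chromosome 17, 85613608 to 85629302, plus strand) changed by -6.54 ± 0.34 from 4.37 CPM, Otx1 by -5.72 ± 0.29 from 6.78 CPM, and Lhx2, a transcription factor of the forebrain, by -2.95 ± 0.17 from 114 to 15.5 CPM. Cartpt (ENSMUSG00000021647, chromosome 13, 99898489 to 99901091, minus strand) went from 229 ± 14.1 to 4.11 ± 1.31 CPM (-5.86 ± 0.16, edgeR adjusted p 7.6e-06). Fgf15, a growth factor of the neural tube, changed by -5.56 ± 0.29. Pou5f1 (ENSMUSG00000024406, chromosome 17, 35506018 to 35510772, plus strand) went from 8.14 ± 3.09 to 0.905 ± 0.362 CPM (-3.13 ± 0.37). Utf1 and Tdgf1, markers of pluripotent cells, changed by -4.45 ± 0.31 and -6.17 ± 0.59. Msx1 and Wnt3a, which are expressed in the dorsal neural tube, changed by -3.49 ± 0.54 and -3.26 ± 0.37.

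**Figure D1:**
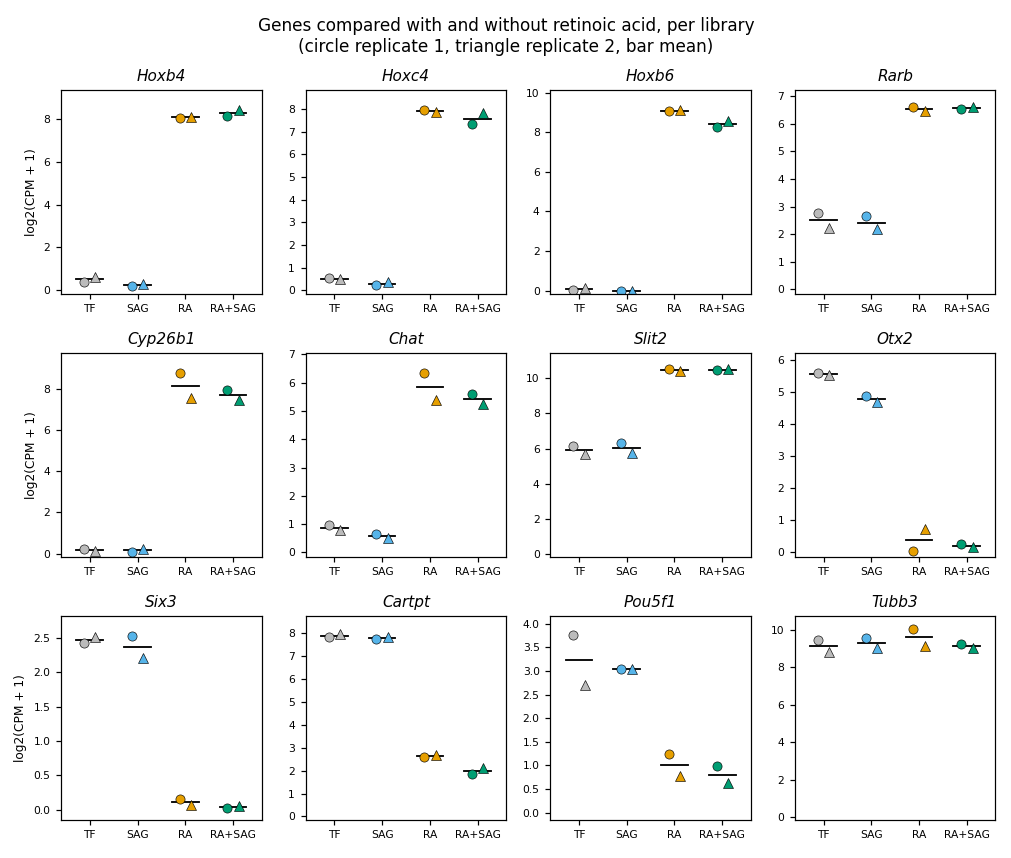
Levels of 12 genes in the 8 motor neuron libraries as log2(CPM + 1), with a circle for replicate 1, a triangle for replicate 2 and a bar for the mean of TF, TF+SAG, TF+RA and TF+RA+SAG. Hoxb4 lies at 0.312 CPM on average without RA and 288 CPM with it, Otx2 at 36.2 and 0.235 CPM, and Tubb3 at 600.4 and 679.5 CPM.

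As gene groups, all 14 tested members of the list of Hox paralogues 1 to 5 passed as higher with RA (14 adjusted over the list alone), with a median log2 fold change of 9.33 (camera adjusted p 8.4e-144, and 0.00612 with an estimated correlation). Of 17 tested retinoic acid response genes, 16 were higher and 1, Rarg, did not pass, whereas 17 passed adjusted over the list alone (4.4e-45; 0.00575 estimated). Of 11 Hox paralogues 6 to 13, 9 were higher and 2, Hoxc9 and Hoxc13, did not pass. Adjusted over the list alone, 10 were higher and 1 lower (2.7e-26; 0.0368 estimated, and 0.0598 with the block), and the median was 5.18, or 3.66 with 1 member at its bound. Of 14 pluripotency genes, 9 were lower and 5 did not pass (10 lower adjusted over the list alone; 4.2e-11; 0.0368 estimated, and 0.0863 with the block). Motor neuron genes gave 10 higher, 1 lower and 5 not passed of 16 (11 and 2 adjusted over the list alone, 3.7e-14), with adjusted p = 0.128 with an estimated correlation. The 1 lower was Ache, which encodes acetylcholinesterase, and the 5 were Mnx1, Isl1, Lhx3, Neurog2 and Cbln1. Ache, Cbln1, Rarg, Hoxc9 and Hoxc13 were named after their values had been seen. Fore- and midbrain genes gave 6 lower and 7 not passed of 13 (9 lower adjusted over the list alone, 1.6e-13), with adjusted p = 0.0575 with an estimated correlation. Dorsal neural tube genes gave 4 lower and 5 not passed of 9, namely Olig3, Wnt3a, Pax3 and Msx1 as lower (5 adjusted over the list alone, 1.4e-04), with adjusted p = 0.444 with an estimated correlation. The glia list (adjusted p 0.00898, Aqp4 lower) and the early endoderm and mesoderm list (0.0208, Cldn6 and Foxa2 lower) had adjusted p = 0.273 with an estimated correlation, with 5 members each lower adjusted over the list alone. The 4 calls that hold with an estimated correlation without a block are therefore Hox paralogues 1 to 5, retinoic acid response, Hox paralogues 6 to 13 and pluripotency, and the first pair also hold with the block (0.0334 and 0.0457). Of 18 pan-neuronal genes, Syt1 and Mapt were higher and 16 did not pass. None of 20 cell cycle genes passed in edgeR. For sensory and dorsal neuron genes the median (0.12) was above 0, while the mean and the test pointed down.

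The smoothened agonist contrast asks how Hedgehog activation changes the same cultures, averaged over those with and without RA. Fewer genes passed than for RA, and those that rose include a direct readout of the pathway. Gli1, a Hedgehog transcription factor that is also its target, rose with SAG. Nkx6-1 and Nkx2-9, which mark ventral progenitors, rose, and Dbx1, which marks progenitors of intermediate position, fell. Trf, which carries iron in blood, and Apoa4, an apolipoprotein, fell, and clusters led by the endoderm gene Ttr held 3.24 to 10.4% of UMIs in libraries with SAG and 6.06 to 16.6% in those without.

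Of 14827 genes, 26 passed (edgeR quasi-likelihood, Benjamini-Hochberg), 11 higher and 15 lower with SAG, and 1480 passed with the replicate block (524 higher, 956 lower). No gene passed in edgeR without TF replicate 1, TF replicate 2, TF+SAG replicate 1, TF+RA+SAG replicate 1 or TF+RA+SAG replicate 2. Between 4 and 5 passed without TF+RA replicate 1 (5), TF+RA replicate 2 (4) or TF+SAG replicate 2 (5). Against these counts of 0, 1125 genes had an unadjusted p under 0.05 with all libraries, and DESeq2 called 352. Gli1 (ENSMUSG00000025407, chromosome 10, 127329882 to 127341974, minus strand) was at 5.65 ± 2.01 CPM (SD, n = 4) with SAG and 0.998 ± 0.641 (n = 4) without, a log2 fold change of 2.73 ± 0.25 (SE, adjusted p 0.0216; 6.5e-06 with the block). Nkx6-1 (ENSMUSG00000035187, chromosome 5, 101658139 to 101664996, minus strand) rose from 26.0 ± 0.989 to 60.6 ± 4.68 CPM (1.22 ± 0.12, 0.0216; 3.1e-06 with the block). Nkx2-9 (ENSMUSG00000058669, chromosome 12, 56611389 to 56613284, minus strand) rose from 0.778 ± 0.533 to 18.5 ± 13.1 CPM (4.63 ± 0.41, 0.0216; 5.8e-05 with the block). Angpt1, a vascular growth factor, rose from 4.72 ± 3.50 to 12.8 ± 4.69 CPM (1.75 ± 0.19, 0.0338). Dbx1 (ENSMUSG00000030507, chromosome 7, 49631499 to 49636849, minus strand) went from 1.38 ± 0.458 to 0.0378 ± 0.0116 CPM (-5.11 ± 0.44, 0.0212). Trf (ENSMUSG00000032554) changed by -2.70 ± 0.28 from 1.99 CPM (0.0323) and Apoa4 (ENSMUSG00000032080) by -2.68 ± 0.30 from 1.95 CPM (0.0399). Slc40a1, an iron exporter, went from 10.8 ± 1.94 to 3.58 ± 0.599 CPM (-1.59 ± 0.18, 0.0399), and Mt2, a metallothionein, from 127 ± 31.0 to 53.2 ± 4.55 CPM (-1.23 ± 0.14, 0.0365).

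Several genes of the same pathways passed with the replicate block and not without it. Ptch1, the main Hedgehog receptor, was at 72.9 ± 26.3 CPM with SAG and 17.9 ± 6.38 without (2.03 ± 0.32, edgeR adjusted p 0.0676; 3.0e-08 with the block). Rab34, a regulator of cilia, had 1.12 ± 0.16 (0.0627; 6.5e-06 with the block), Nkx6-2 2.03 (0.0627; 1.9e-05) and Nkx2-2, a marker of the most ventral progenitors, 2.95 ± 0.46 (0.0676; 3.3e-04). Olig2, which marks motor neuron progenitors, had 3.12 ± 0.45 (0.0627; 0.00695). Its level was 50.8 and 41.3 CPM in the TF+RA+SAG libraries and 1.90 CPM or less in the other 6 libraries. Pax3, a dorsal gene, had -3.34 ± 0.47 (0.0627; 3.2e-04). Fabp1 and Hnf4a, genes of liver and endoderm, had -4.11 ± 0.60 (0.0627; 7.2e-04) and -2.31 ± 0.36 (0.0658; 6.9e-05). Isl1 had 0.48 ± 0.14 (0.329; 0.0026), while Mnx1 (-0.03, 1.0) and Chat (-0.64, 0.736) did not pass in edgeR with the block either (0.998 and 0.0898).

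**Figure D2:**
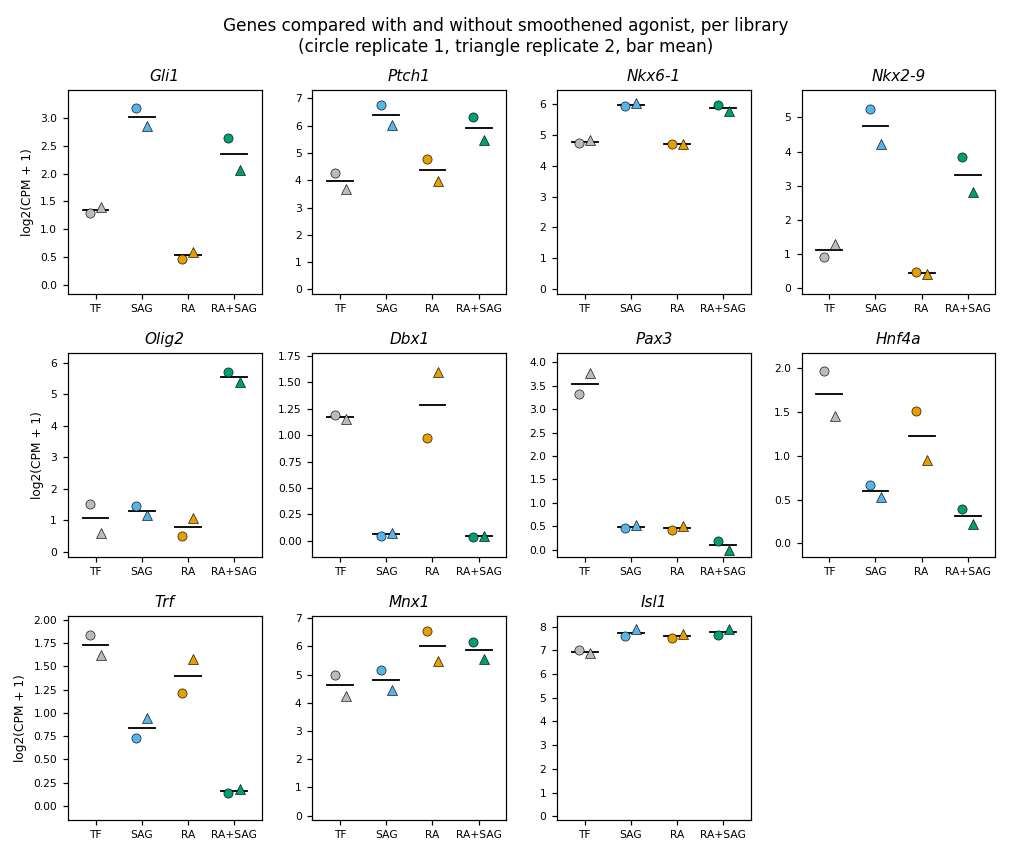
Levels of 11 genes in the 8 motor neuron libraries as log2(CPM + 1), with a circle for replicate 1, a triangle for replicate 2 and a bar for the mean of TF, TF+SAG, TF+RA and TF+RA+SAG. Nkx6-1 averages 60.6 CPM with SAG and 26.0 CPM without, and Olig2 is at 50.8 and 41.3 CPM in the TF+RA+SAG libraries and at 1.90 CPM or less elsewhere.

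Of 12 tested Hedgehog target genes, 2 were higher with SAG, among them Gli1, and 10 did not pass, whereas 7 were higher and 1 lower adjusted over the list alone (median 0.77, camera adjusted p 1.0e-23; 0.0209 with an estimated correlation). Ventral neural tube genes gave 2 higher, Nkx2-9 and Nkx6-1, and 13 not passed of 15 (9 higher adjusted over the list alone; median 0.97, 1.0e-23; 0.0209 estimated). Of 15 hepatocyte list genes, 1 was lower, Trf, and 14 did not pass (13 lower adjusted over the list alone; median -2.62, 3.7e-43; 0.0209 estimated). Of 8 intestinal epithelium genes, 1 was lower, Apoa4, and 7 did not pass (5 adjusted over the list alone; median -2.25, 6.6e-12; 0.0292 estimated). No member passed over all genes in edgeR for epithelial junction genes (5 of 15 lower adjusted over the list alone; 6.5e-10; 0.0209 estimated) or fore- and midbrain genes (4 of 13 lower; 4.6e-09; 0.0209 estimated). The same held for cholesterol synthesis genes (1 of 16 higher; median 0.32, 1.1e-06; 0.0292 estimated), early endoderm and mesoderm genes (3 of 8 lower; 1.8e-06; 0.0292 estimated) and spinal interneuron genes (3 of 11 lower; 3.1e-06; 0.0292 estimated). These 9 are the list calls, of 22, that hold with an estimated correlation, and with the replicate block none does, the smallest adjusted p being 0.114. Dorsal neural tube genes gave 1 lower, Dbx1, and 8 not passed of 9 (4 lower adjusted over the list alone, 2.1e-12), with adjusted p = 0.0791 with an estimated correlation. The motor neuron list was not called (adjusted p 0.193), and its median (-0.01) and mean (-0.02) lay below 0 while its test pointed up.

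Whether the RA effect differs with and without SAG was tested as an interaction. No gene passed in edgeR. Without a block, an unadjusted p under 0.05 was found for 587 of 14827 genes, a share no larger than chance would give. With the replicate block it was found for 3292. The fit without a block leaves the replicate difference unmodelled, so its share does not show the absence of an interaction. DESeq2 called 24 and the replicate block 692 (378 higher, 314 lower). RA and SAG together against TF alone (2 libraries each, dispersion shared over all 8) changed 1249 genes, 473 higher and 776 lower, and 4734 with the block. This count fell to 515 without TF replicate 1, 584 without TF replicate 2, 387 without TF+RA+SAG replicate 1 and 438 without TF+RA+SAG replicate 2. Hoxb4 rose by 9.51 and Chat by 5.63 on the log2 scale (edgeR adjusted p 0.00102 for Chat), and Olig2 by 5.17 (0.00486), while Pax3 changed by -6.83 (0.00233) and Otx2 by -8.19. RA alone against TF alone changed 1032 genes, 549 higher and 483 lower, and 5480 with the block. Its count fell to 336 without TF replicate 1, 451 without TF replicate 2 and 424 without TF+RA replicate 1. RA alone raised Hoxb4 by 9.30, Chat by 6.14 and Slit2 by 4.55, and Otx2 changed by -7.50. SAG alone against TF alone changed no gene in edgeR, with 927 at an unadjusted p under 0.05, 186 called by DESeq2 and 928 with the block. In that comparison Nkx2-9 had a log2 fold change of 4.55 (0.109; 4.0e-04 with the block) and Ptch1 of 2.49 (0.183; 2.2e-07 with the block). The difference between the counts of RA alone and SAG alone was not tested.

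Clusters led by pan-neuronal markers that met the naming rule were called neuron-like. They were clusters 1 and 8, which held the class without RA, and 14, 3, 4 and 10, which held it with RA. Clusters 2 and 7 also reached the marker ratio but stayed unnamed, with medians of 1288 and 1939 UMIs. Cluster 2 held 83.3% of cells in TF+RA replicate 1, 13.1% in TF+RA+SAG replicate 1 and 3.01% or less elsewhere. Cluster 7 held cells only without RA. In the shares below, cells of both clusters were not counted as neuron-like. Of cells with 2000 or more UMIs, 46.0 ± 4.91% (SD, n = 4 libraries) were neuron-like with RA and 47.9 ± 6.94% without (exact permutation p 0.629), and 49.3 ± 5.84% with SAG and 44.6 ± 5.06% without (exact permutation p 0.314). Among named cells, a denominator chosen after seeing the data, both differences turn sign, to 5.71 points for RA (exact permutation p 0.657) and -6.86 points for SAG (exact permutation p 0.514). Within these cells RA changed 1907 of 13283 genes (edgeR quasi-likelihood, Benjamini-Hochberg), 1060 higher and 847 lower, and 5402 with the replicate block, of which 1897 were among the 1907. The count was 1218 without TF+RA+SAG replicate 1 and 1211 without TF+RA+SAG replicate 2. Chat rose by 6.49 ± 0.28 (SE, adjusted p 2.7e-05), Hoxb4 by 11.61 ± 0.38, Slit2 by 4.48 and Rarb by 3.86 ± 0.23. Mecom rose by 6.23, while Otx2 changed by -7.09 and Cartpt by -6.26. Mnx1, which did not pass over all cells, passed here with 1.14 (0.0282). Pou5f1 did not (-0.14, 0.932). Motor neuron genes gave 10 higher, 1 lower (Ache) and 5 not passed of 16 (11 and 1 adjusted over the list alone), with adjusted p = 0.0841 with an estimated correlation and 0.015 with the block as well. Within neuron-like cells 322 of 13283 genes had an unadjusted p under 0.05 with SAG without a block, a share no larger than chance would give. With the replicate block 1322 had one. SAG changed no gene there in edgeR, with 6 called by DESeq2 and 108 with the block (42 higher, 66 lower). The block called Ptch1 (1.31, adjusted p 1.9e-07), Angpt1 (1.77, 2.2e-07) and Nkx2-9 (4.62, 4.2e-04) there, whose adjusted p without it was 0.673 or more.

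At 2000 UMIs per cell, 10.6 ± 5.21% of cells (SD, n = 4) had a Chat UMI with RA and 0.166 ± 0.161% without. The exact permutation p was 0.0286, the smallest the design allows, or 0.0686 adjusted over 84 measures. All 4 libraries with RA lay above all 4 without, with differences of 13.5 points in replicate 1 and 7.38 in replicate 2. Between 89 and 12817 cells per library were left out by thinning, and unthinned shares were 24.5 ± 6.69% and 0.845 ± 0.378%. In neuron-like cells the Chat shares were 16.5 ± 6.92% and 0.288 ± 0.236%. In clusters 6 and 13, which were led by the endoderm gene Ttr and should lack Chat, they were 1.34 ± 1.56% with RA and 0 without. Median depths were 12412 and 6474 UMIs in those clusters, and 12079 in neuron-like cluster 14. Hoxb4 was found in 44.0 ± 1.75% of cells with RA and 0.0469 ± 0.0938% without (unthinned 66.8 ± 18.4% and 0.412 ± 0.288%), and in 5.88% of cells of the Ttr clusters with RA. Mnx1 was found in 12.4 ± 4.55% with RA and 5.81 ± 1.81% without, while its unthinned shares, 30.9 ± 9.54% and 24.8 ± 9.34%, overlapped (exact permutation p 0.429). The thinned shares have the same exact permutation p of 0.0286, or 0.0686 adjusted, so none passes after adjustment. As 0.0286 is the smallest p the design allows, no measure could pass over 84 by the size of its own difference alone. The adjusted p therefore does not weigh that size. Slc18a3, the acetylcholine transporter, was found in 38.7 ± 14.02% with RA and 2.66 ± 0.910% without (unthinned 57.8 ± 4.58% and 10.5 ± 4.01%). With SAG, Nkx6-1 was found in 10.6 ± 0.974% of cells against 5.65 ± 0.339% without (unthinned 34.0 ± 5.71% and 18.2 ± 8.12%), and Ptch1 in 12.1 ± 3.43% against 3.62 ± 1.72% (unthinned 36.6 ± 10.1% and 13.2 ± 4.69%). Each of these SAG contrasts has an exact permutation p of 0.0286 and 0.24 after adjustment.

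The Matrigel contrast asks how a Matrigel sandwich changes expanded induced endoderm progenitors, with 2 libraries on each side. Col1a1 and Col3a1, which encode fibrillar collagens, Dcn, which encodes a proteoglycan of connective tissue, and Fosb and Jun, which encode transcription factors induced by acute stimulation, rose. Cdh1, which encodes E-cadherin, Lamb3, a laminin chain, and Msln, a surface protein of mesothelium, fell. Hnf4a, a transcription factor of liver and gut that is also part of the reprogramming construct, fell as well.

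Of 14108 genes, 1780 passed (edgeR quasi-likelihood, Benjamini-Hochberg), 907 higher and 873 lower in Matrigel. The count rests on the libraries: it was 491 (403 higher, 88 lower) without Matrigel replicate 1 and 711 without standard replicate 1. Without Matrigel replicate 2 it was 0 in edgeR, with 3030 genes at an unadjusted p under 0.05 and, with all libraries, 3832 called by DESeq2. The gene tables differ between the conditions (28001 entries against 28002 and 32285), and the software of the standard libraries is doubtful or not given in the sources used here, so culture cannot be separated from processing. Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042, plus strand) rose from 23.1 ± 5.6 (SD, n = 2) to 431 ± 65.2 CPM (n = 2), a log2 fold change of 4.22 ± 0.44 (SE) with an edgeR adjusted p of 0.0155. Col3a1 (ENSMUSG00000026043, chromosome 1, 45311538 to 45349706, plus strand) rose by 7.65 ± 0.60 from 2.44 to 491 ± 223 CPM (0.0155), and Twist1, a mesenchymal transcription factor, by 3.29 ± 0.33. Dcn (ENSMUSG00000019929, chromosome 10, 97479609 to 97518143, plus strand) had 13252 UMIs in Matrigel and 3 in standard culture, a ratio of 2461 (95% interval 842 to 11934), and was at 25.4 and 197 CPM in the Matrigel libraries. Aspn, a related proteoglycan, had a ratio of 2671 (479 to 105508), and Aox3, an aldehyde oxidase, was at least 436-fold higher. Fosb (ENSMUSG00000003545, chromosome 7, 19302696 to 19310051, minus strand) rose from 52.7 ± 8.24 to 639 ± 126 CPM (3.60 ± 0.45, 0.0227), Jun by 3.19 ± 0.49, Fos by 2.53 ± 0.50 and Egr1 by 2.25 ± 0.48. C3, a complement protein (ENSMUSG00000024164, chromosome 17, 57203970 to 57228136, minus strand), had a ratio of 2206 (396 to 87157, edgeR adjusted p 0.0398). Lcn2, an iron-binding protein of inflammation (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252, minus strand), had a ratio of 235 (80.1 to 1139), and Reg3g, an antimicrobial lectin, one of 870.2 (241 to 7188). Klf2, a flow-responsive transcription factor, rose by 4.37 ± 0.42, Col4a1, a basement membrane collagen, by 3.78 ± 0.59 from 31.2 to 430.1 CPM, and Slc1a3, a glutamate transporter, by 8.47 ± 0.71.

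S100a7a, a calcium-binding protein of epithelia (ENSMUSG00000063767, chromosome 3, 90654017 to 90658669, plus strand), went from 109 ± 17.5 to 1.05 ± 0.125 CPM in Matrigel (log2 fold change -6.70 ± 0.40, edgeR adjusted p 0.00954). Msln (ENSMUSG00000063011, chromosome 17, 25748613 to 25754378, minus strand) went from 1824 ± 289 to 81.9 ± 46.6 CPM (-4.48 ± 0.65, 0.0268). Lamb3 changed by -4.13 ± 0.45 (0.0169), Itga3, an integrin that binds laminin, by -3.38 ± 0.39 from 217 to 20.8 CPM (0.0186), and Pgf, a growth factor of the vascular endothelial family, by -5.33 ± 1.13 (0.0490). Cdh1 (ENSMUSG00000000303, chromosome 8, 106603351 to 106670246, plus strand) went from 285 ± 53.9 to 66.3 ± 29.1 CPM (-2.10 ± 0.45, 0.0368). Hnf4a (ENSMUSG00000017950, chromosome 2, 163506808 to 163572910, plus strand) went from 92.8 ± 22.4 to 28.5 ± 5.10 CPM (-1.71 ± 0.34, 0.0349). Nes, an intermediate filament of progenitors, changed by -3.69 ± 0.62 and Ccnd1, a cyclin, by -2.84 ± 0.61. Alb (ENSMUSG00000029368, chromosome 5, 90460897 to 90476602, plus strand) was at 393 ± 138 CPM in Matrigel and 11.9 ± 15.97 CPM in standard culture and did not pass (5.01 ± 1.64, 0.110). Ctgf, a target of YAP signalling, had -3.72 ± 1.42 (0.139). Apoa1, an apolipoprotein, was at 378 and 15650 CPM in the standard libraries and had -1.40 ± 1.54 (0.563). Without standard replicate 2 its log2 fold change was 2.996 (edgeR adjusted p 0.0405).

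**Figure D3:**
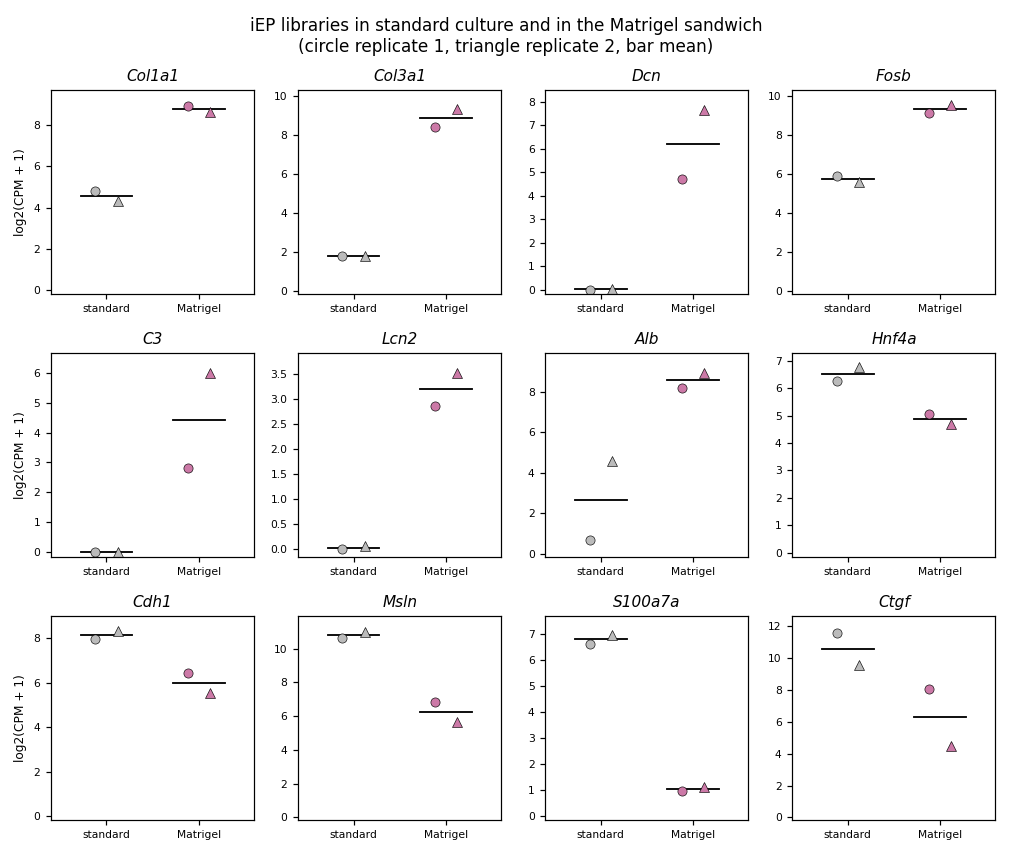
Levels of 12 genes in the 4 endoderm progenitor libraries as log2(CPM + 1), with a circle for replicate 1, a triangle for replicate 2 and a bar for the mean of standard and Matrigel culture. Col1a1 averages 431 CPM in Matrigel and 23.1 CPM in standard culture, and Msln 81.9 and 1824 CPM.

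Of 16 fibroblast list genes, 8 were higher in Matrigel and 8 did not pass (13 higher adjusted over the list alone), with a median log2 fold change of 3.68 (camera adjusted p 4.0e-12; adjusted p = 0.737 with an estimated correlation). The Matrigel libraries lay far apart, with 13.1% of cells of 2000 or more UMIs fibroblast-like in replicate 1 (1020 of 7765) and 60.7% in replicate 2 (2980 of 4906). Immediate early and heat shock genes gave 5 higher and 7 not passed of 12 (8 higher adjusted over the list alone; median 2.04, 2.7e-04; adjusted p = 0.737 with an estimated correlation), namely Fosb, Jun, Fos, Egr1 and Hspa1b as higher. The median mitochondrial share of UMIs per cell, a sign of cell quality, was 10.8 and 8.08% in the standard libraries and 4.93 and 5.85% in the Matrigel libraries. Inflammatory genes gave 3 higher (Lcn2, C3 and Vcam1) and 9 not passed of 12 (3 adjusted over the list alone; 0.0095, and 0.737 with an estimated correlation). Of 22 hepatocyte genes, Fgg (at least 73.9-fold), Asgr1 (at least 35.7-fold), Rbp4 (2.65 ± 0.48) and Fga were higher, Hnf4a was lower and 17 did not pass (6 and 1 adjusted over the list alone; 0.0314, and 0.737 with an estimated correlation). Hox paralogues 6 to 13 gave 5 higher (Hoxd8, Hoxa7, Hoxd10, Hoxd9 and Hoxa10, the last at 1.35 ± 0.30) and 11 not passed of 16 (8 higher and 1 lower adjusted over the list alone; 0.0354, and 0.737 with an estimated correlation). The cranial motor neuron list (1 of 5 higher, Tbx3; 2 adjusted over the list alone; 0.0354) and the spinal interneuron list (Lhx1 and Gad2 of 6 higher; 4 higher and 1 lower adjusted over the list alone; 0.0422) were called as well. None of these 7 calls holds with an estimated correlation (0.737 for these lists as well). Epithelial junction genes gave 1 lower (Cdh1) and 11 not passed of 12 (0.148). Basement membrane and integrin genes moved both ways, with Col4a1 and Col4a2 higher, 4 lower (among them Lamb3, Itga3 and Lama5) and 9 not passed of 15 (0.175). YAP target genes gave 1 lower (Ajuba) and 16 not passed of 17 (0.148), and 0 of 20 cell cycle genes passed. For intestinal epithelium genes the median (-0.93) was below 0 while the mean and the test pointed up. List members outside the naming rule, such as Hspa1b, Fga, Hoxd9, Col4a2 and Lama5, were named after their values had been seen.

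**Figure D4:**
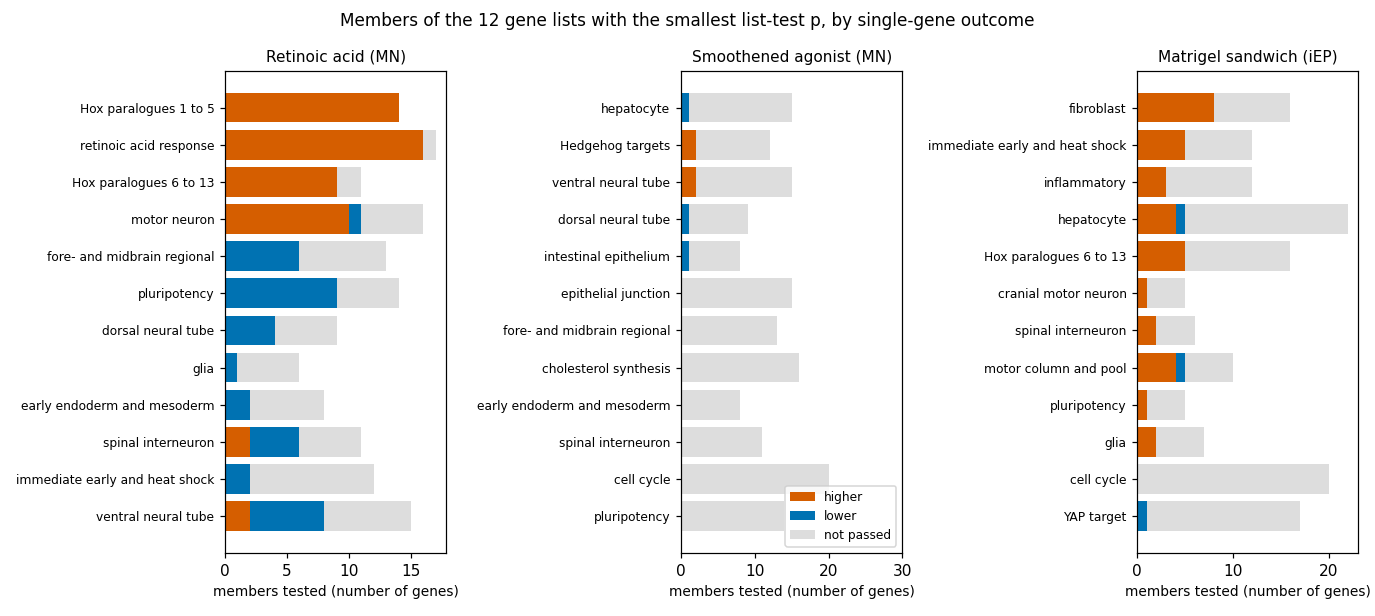
Number of genes higher, lower and not passed (stacked bars, edgeR adjusted p of 0.05) in the 12 lists with the smallest p-values of the list test of each contrast, in panels for RA, SAG and Matrigel. Among Hox paralogues 1 to 5, 14 of 14 tested genes were higher with RA, and of 16 fibroblast genes 8 were higher in Matrigel.

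The day 14 induced cardiomyocyte (iCM) libraries were measured for the cardiac programme without a comparison group. Mef2c, Gata4 and Tbx5 encode the transcription factors commonly used for this conversion, and Tnnt2 encodes a thin filament protein of the sarcomere. At 2000 UMIs per cell, Mef2c was found in 24.1% of 1189 cells of replicate 1 and 35.7% of 4007 cells of replicate 2. The 95% exact intervals are 21.6 to 26.6% and 34.3 to 37.2%. Thinning left out 223 and 343 cells. Without thinning, Mef2c was found in 36.97% and 54.9% of cells and Tnnt2 in 26.8% and 46.8%. Tnnt2 was found in 17.3% and 29.1% of cells (mean 23.2%, SD 8.34, n = 2), Gata4 in 3.78% and 8.14%, and Tbx5 in 5.13% and 11.2%. Atrial Myl4 was found in 12.4% and 15.2% and Myl7 in 3.87% and 6.74%. Myh6, the main cardiac myosin, was found in 0.168% and 0.200%, Actc1, cardiac actin, in 1.60% and 0.998%, and Nppa in 0 of 1189 cells and 2.07% of 4007. Ventricular Myl2 was found in 0 of 1189 cells (exact 95% upper limit 0.310% for cells with a UMI at this depth, not for cells that express it) and in 0.0250% of 4007, with 3 and 4 UMIs in the libraries before thinning. In the 636 immune-like cells of replicate 2 (clusters 8 and 10, median 3433 and 14366 UMIs), which should lack these genes, a separate thinning found a UMI of Mef2c in 28.1%, of Tnnt2 in 11.9%, of Gata4 in 2.67% and of Col1a1 in 21.9%. Mef2c is also expressed by immune cells, so its share there is not background alone. Cardiomyocyte-like cluster 6 had a median of 12077 UMIs. It held 0.354% of clustered cells in replicate 1 (5 of 1411) and 15.1% in replicate 2 (656 of 4342). Cardiomyocyte-like cluster 9 held 0.213% and 13.4%. Nearly all cells of these clusters therefore came from replicate 2, and the mean Tnnt2 share does not show this difference. Libraries were not integrated, and other clusters also lay mostly in 1 library, such as cluster 1 (41.0% and 0.553%) and cluster 7 (1.13% and 23.9%). Gene levels differed less and not in 1 direction. Tnnt2 was at 348 and 583 CPM, Myl7 at 54.8 and 59.9 CPM and Actc1 at 57.3 and 8.75 CPM. Whether the cluster shares reflect cell type or library differences cannot be told.

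By gene list, cardiomyocyte genes summed to 623 CPM in replicate 1 and 734 CPM in replicate 2, with 7 and 6 of 20 members at 10 CPM or more. Atrial genes summed to 587 and 744 CPM (5 and 6 of 11 members), while ventricular genes summed to 9.73 and 4.33 CPM with no member of 7 at 10 CPM. The cardiomyocyte sum is mostly Tnnt2 (348 and 583 CPM), and the largest part of the atrial sum is Myl4 (329 and 383 CPM). Fibroblast genes were far more abundant, at 13876 and 11820 CPM (14 and 15 of 16 members), as were activated fibroblast genes at 24721 and 11538 CPM and smooth muscle genes at 7744 and 5422 CPM. The smooth muscle sum is mostly Acta2 (4050.0 and 2125 CPM) and Tagln (3504 and 3074 CPM), which the activated fibroblast list also holds, while Myh11 and Cnn1 were at 54.7 and 34.4 CPM in replicate 1 and 1.70 and 13.8 CPM in replicate 2. These 4 genes were named after their values had been seen. Col1a1 was found in 79.8% and 47.5% of cells and Postn, a matrix protein of activated fibroblasts, in 6.22% and 1.75%. Immune genes summed to 250.4 and 1776 CPM and epicardial genes to 524 and 1648 CPM.

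**Figure D5:**
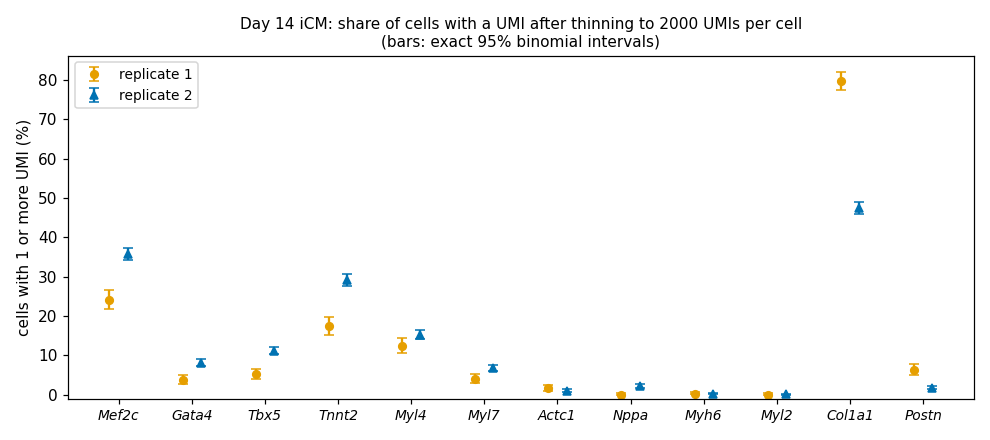
Percent of day 14 induced cardiomyocyte cells with at least 1 UMI of each of 12 genes after thinning to 2000 UMIs, with bars of exact 95% intervals for replicate 1 (1189 cells) and replicate 2 (4007 cells). Tnnt2 is found in 17.3% and 29.1% of cells and Myl2 in 0 and 0.0250%.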

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

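Both construct tests of this part were set before their results were seen, and the replicate block was chosen before the differences between cultures with and without SAG were seen.

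The RA effect was compared between cultures with and without SAG. Without a block no gene passed in edgeR (587 at an unadjusted p under 0.05, no more than chance would give, and 24 called by DESeq2). The fit with the replicate block gave 3292 genes at an unadjusted p under 0.05. With the replicate block, the difference between the RA effect with SAG and without it was 5.97 on the log2 scale for Olig2 (edgeR adjusted p 0.0211; RA effect without SAG -1.04) and 0.62 for Neurog2, a proneural factor (0.0298; -0.51 without SAG). It was -0.94 for Ptch1 (0.00807; 0.46 without SAG) and -0.62 for Isl1 (0.0458; 0.66 without SAG). At the level of lists, the median difference was 0.89 for Hox paralogues 1 to 5 (0.89 as well without the 3 members at 0 in a group), 1.32 for fore- and midbrain genes and -0.048 for ventral neural tube genes. It was -0.62 for motor neuron genes, -0.70 for pan-neuronal genes, 0.58 for neural progenitor genes and 0.58 for cell cycle genes. Immediate early and heat shock genes gave 0.37, hepatocyte genes -0.80, basement membrane and integrin genes 0.75 and hypoxia genes 0.21. None of these list differences holds with an estimated correlation, where the adjusted p runs from 0.376 to 0.673. No biological explanation was tested for these differences.

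Sequences of the reprogramming vectors had UMIs outside the endoderm progenitor libraries. In the 4 motor neuron libraries of replicate 2 the CellTag sequence averaged 3.14 CPM (2.62 to 3.46) and the GFP sequence 35.2 CPM (29.3 to 41.1). In day 14 cardiomyocyte replicate 1 they were at 0.9496 and 0.422 CPM, and the FoxA1.HNF4a sequence at 226 CPM. All 3 sequences were listed with 0 UMIs in the 4 motor neuron libraries of replicate 1, and FoxA1.HNF4a in all 8 motor neuron libraries. In the 2078 barcodes of the cardiomyocyte library the counts were 9 UMIs in 4 barcodes for CellTag, 4 UMIs in 2 barcodes for GFP and 2144 UMIs in 519 barcodes for FoxA1.HNF4a, and no background level was set against them.

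The FoxA1.HNF4a sequence in cardiomyocyte replicate 1 was weighed further. RNA or cells carried over from the endoderm progenitor libraries would bring their other abundant transcripts. Over 50 genes abundant in those libraries the median ratio of levels was 0.0259, against 0.590 for the construct, which argues against carry-over as the whole source. A candidate explanation is vector sequence shared with the virus of the cardiac factors: cells with a Mef2c, Gata4 or Tbx5 UMI had a construct UMI more often (50.9% of 338 against 9.47% of 834, odds ratio 9.88, 95% interval 7.14 to 13.7). No biological explanation was tested.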

How the results depend on the processing

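Leaving out cells over 60000 UMIs, leaving out the clusters led by Ttr and the other denominators of the neuron-like share were chosen after seeing the data.

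Genes changed. With the replicate block the counts were 5868 for RA, 1480 for SAG, 692 for the interaction, 4734 for RA and SAG together, 5480 for RA alone, 928 for SAG alone, and 5402 (RA) and 108 (SAG) in neuron-like cells. For Matrigel it was 2349. DESeq2 gave 352 for SAG, 24 for the interaction, 1633 for RA alone, 186 for SAG alone, 6 for SAG in neuron-like cells and 3832 for Matrigel. Without the low-count filter there were 179 for SAG, 57 for SAG alone, 2 for SAG in neuron-like cells and 2954 for Matrigel. SAG gave 15 with library sums thinned to the smallest, 63 with the strict cell filter, 9 without cells over 60000 UMIs and 10 without the clusters led by Ttr. The cause was not tested for any of these. Leaving out each library in turn, which leaves fewer samples, gave 1136 to 1661 for RA, 0 to 5 for SAG, 0 for the interaction, 387 to 1260 for RA and SAG together, 336 to 909 for RA alone and 0 for SAG alone. In neuron-like cells it gave 1211 to 1573 for RA and 0 for SAG, and for Matrigel 0 to 2327. A lone sample is then assumed to vary like the other groups. For the interaction and for SAG in neuron-like cells, the genes with an unadjusted p under 0.05 were no more than chance would give without a block. With the block they numbered 3292 and 1322. The counts of 0 are edgeR's; with all libraries 587 (interaction), 927 (SAG alone) and 322 (SAG in neuron-like cells) had an unadjusted p under 0.05, and Matrigel without its replicate 2 had 3030.

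Gene lists called. With an estimated correlation 4 lists were called for RA, 9 for SAG and 0 for Matrigel. With the preset correlation the counts were 9, 22 and 7, and leaving out each library then gave 9 to 12, 21 to 24 and 9 to 13.

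Shares. The neuron-like difference with RA was 5.71 points among named cells against -1.91 (-4.59 to 0.639 leaving out each library, the last without TF+SAG replicate 2). Among all filtered cells the RA difference lay below that range, with 83.3% of TF+RA replicate 1 in cluster 2, which was left unnamed. With SAG the difference was -6.86 among named cells and 12.4 among all filtered cells against 4.74 (2.66 to 7.30). The Chat difference with RA was 6.06 points thinned to 1000 and 23.7 not thinned (7.90 to 11.6), and for Nkx6-1 with SAG 2.85 and 15.9 (4.70 to 5.37). Fewer UMIs per cell lower each share by construction. The Tnnt2 share of cardiomyocytes was 17.3 to 29.1%. The cause of the differences between denominators was not tested.

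Named genes. Apoa1 in Matrigel reversed to 2.996 without standard replicate 2 (-2.40 without standard replicate 1), and the cause was not tested. Of the alternatives of called genes, 1971 kept the call and 169 lost it for RA, 99 and 90 for SAG, and 842 and 205 for Matrigel.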

Other observations

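Tests chosen after their results were seen are those on the clusters led by Ttr with their paired error and on cluster 6 alone, the background of the construct, on the fibroblast-like cells of Matrigel replicate 2 and on the software versions, and the test on Matrigel replicate 1 was limited to that library after its value was seen.

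The 8 motor neuron libraries can be split into 4 and 4 in 35 ways. In a model with the split alone, 2 of the 35 splits gave as many genes as RA (1863), so chance cannot be excluded by this count. The other was the replicate number with 4136 genes, and the next had 2. The replicate number coincides with the software version, and a split that calls so many genes points to a structure of the samples. Among the 18 splits that divide each replicate number evenly, fitted with the replicate block, RA gave 3523 genes and the highest other, SAG, 4. For SAG, 3 of the 35 splits gave as many genes as the real one (2, against 4136 for the replicate number and 1863 for RA). Those 3 are SAG itself and known factors of the samples, and every other split gave 0. The model with the split alone leaves the RA effect and the replicate difference unmodelled, and called 2 genes where the planned model called 26. It therefore cannot decide whether chance explains the planned SAG calls. With the block SAG gave 4. In neuron-like cells 2 of 35 splits gave as many genes as RA (2458, against 3928 for the replicate number). With the block RA gave 5006 genes there and the highest other 0. For SAG 35 of 35 splits gave as many (0 genes in edgeR, with 6 called by DESeq2 in the full model). With a real count of 0 this was fixed in advance, so it cannot decide anything. In the planned edgeR model without a block 322 genes had an unadjusted p under 0.05, no more than chance would give, and with the block 1322. For gene lists, 20 of 35 splits gave as many called lists as RA (9, against 20 for SAG), and 1 of 35 as many as SAG (20, against 19). That count ignores the pairing of samples by replicate number. Among the 18 even splits with the replicate block SAG gave 19 lists and the highest other 17, and 18 splits are too few for a share under 0.05.

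Hepatocyte list genes were lower with SAG, with a median log2 fold change of -2.62 over 15 tested genes, 14 of them below 0. The clusters led by Ttr (6 and 13) held 3.24 to 10.4% of UMIs in libraries with SAG and 6.06 to 16.6% without, a log2 ratio of -0.96 (SE 0.166 over 4 pairs within replicate number and RA, all below 0; 0.491 without the pairs). Cluster 13 held 102 cells in TF+SAG replicate 2 and at most 3 in any other library, and in cluster 6 alone the ratio was -1.18 (SE 0.187), so fewer UMIs from these clusters stay open as a cause. The list had a median of -1.63 within these clusters and -1.97 in cluster 6 alone, with all 14 tested members below 0 in both, so lower levels inside them may contribute. Without these clusters the median was -1.87 over 10 tested genes (camera adjusted p 1.9e-09, and 0.156 with an estimated correlation). In neuron-like cells it was -1.18, with all 7 tested members below 0 (camera adjusted p 2.5e-08, and 0.0492 with an estimated correlation). Lower counts of the list were therefore also found in barcodes outside the clusters led by Ttr. Whether the RNA counted there was made in those cells was not tested. Whether SAG acts on cells of the Ttr clusters directly was not tested.

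Fibroblast list genes were higher in Matrigel. In Matrigel replicate 1, 29.0% of fibroblast-like cells had a construct UMI (296 of 1020, 95% exact interval 26.2 to 31.9) against 21.9% of the other cells, and standard unnamed cells had 56.02 and 43.0%. Fibroblast-like cells held 2.69 FoxA1.HNF4a UMIs each (95% interval 2.49 to 2.90) and barcodes under 1000 UMIs 0.110 (0.0865 to 0.133), not scaled to depth. Kept cells of that library had a median of 11831 UMIs, and the lowest share in a larger cluster was 17.1% (28 of 164 cells). If background adds as many UMIs to a deep barcode as to a shallow one, this argues against cells that never took up the construct as the whole cause there. A background that grows with depth was not tested. Such cells stay open as a part of the cause (143 CPM in that library, 454 and 312 CPM in standard culture). In replicate 2, 60.7% of cells were fibroblast-like against 13.1% in replicate 1, but its gene table holds no construct, so such cells stay open as an explanation for that library. The conditions share 0 named software versions, but none is named in the files of the standard libraries and only the gene tables are known to differ, so differences in processing stay open as well.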
